A study of Mus musculus with 18 samples.

How the data were processed

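Messenger RNA levels were measured in 18 kidney libraries of ICR mice in 6 groups of 3. Per the labels' protocols, RNA was taken from frozen kidney with Trizol and a column kit and 1 µg of total RNA went into each Illumina library. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.2 to mm10. The counting program, the annotation and the normalization are not given in the sources used here.

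The authors deposited 1 table of normalized signal values per gene symbol and library, with 2 decimals, and state no unit for them. From the values, the sums of the 18 columns had a coefficient of variation of 3.49%, and 0.815% after each value was multiplied by the length of the gene's transcript, which 97.2% of the table's rows had. The signal was therefore treated as normalized for length and depth. Another normalization that gives the same sums was not excluded. Of all values 17.2% were 0, and a gene at 0 is called listed at 0. The table had 19545 entries. A spreadsheet had turned 26 symbols into dates, and these and 1 second entry of a repeated symbol were left out, which left 19518 genes. Of these symbols 18990 (97.3%) were found in GENCODE M21, and coordinates are from that annotation, on GRCm38 (mm10). Reads of near-identical copies, such as those of the haemoglobin and Cyp4a families, cannot be assigned with certainty. Whether reads of other genes map uniquely was not tested.

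The number of reads is unknown, so no counting interval is given for any value. Low values of 100 genes came in whole multiples of a step per gene, with 91.8% of values within 0.1 of a whole number, against 44.7% after random factors on each value. Comparing steps between libraries gave a relative depth of 0.87 (5th to 95th percentile of 100 bootstrap draws over genes, 0.861 to 0.877) for control replicate 3, 0.901 (0.889 to 0.91) for control replicate 1, and 0.971 to 1.031 for the other libraries. The choice of these 100 genes was settled after the values had been seen and earlier choices had given a lower share of whole values. Control replicates 1 and 3 are the shallowest libraries, so their low values carry the largest counting error.

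The groups, comparisons, tests, gene lists and the other settings below that are called planned were fixed before the data were examined. Genes with a value of at least 1 in 3 or more libraries were kept (12031). The log2(value + 1) values of all 18 libraries were fitted in 1 linear model with 6 groups and 12 residual degrees of freedom in limma 3.58.1 (R 4.3.3), with trend and robust estimation of the spread, two-sided tests, and Benjamini-Hochberg adjustment within each of 8 contrasts at a threshold of 0.05. The plan had named this test for normalized values in known units and was followed for the signal. An F test over the 6 groups was fixed with them. All adjusted p-values per gene are from limma. Of 33 fixed gene lists, the 30 with at least 3 measured members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast. Camera compares a list with all other genes. Camera with an estimated correlation and fry were run beside it. The estimated correlation and the test of fry for a common direction called 0 lists in all 8 contrasts. The test of fry for change in either direction called 2 lists in HFD+AOS-FMT against HFD, 4 in HFD+AOS against HFD, 8 in HFD+AOS-FMT against control and 0 in the other 5.

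The genes named in the text follow a rule. Among genes that passed, whose 2 groups did not overlap and whose mean was at least 1, the 12 with the largest increase and the 12 with the largest decrease were named, with predicted genes and pseudogenes passed over and counted. For every list, up to 4 members with the smallest p were named that passed over all genes or over the list alone. Where fewer than 10 genes passed in a contrast, the 10 with the smallest p were named and said not to pass where they did not. Some genes that the rule selects are not reported here. Genes of single libraries (Kap, Star, Havcr1, Lcn2), Adipoq and the immune, haemoglobin and brown fat genes among the other observations were chosen after their values had been seen.

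The test was tried on simulated data for HFD against control with 50 of 12031 genes changed at each size. It recovered 60% at a log2 change of 0.5, 88% at 1, 100% at 2 and 98% at 3, with 3 false calls (1.70% of calls). A shift of 0.7 put into 1 list was found (adjusted p = 4.45e-16) with 0 other lists called. The simulated noise was independent between genes and held no outlying library. The trial therefore cannot show how often the list test calls lists falsely where genes are correlated. For the comparison of diet and treatment effects, unchanged groups were simulated from the residuals of the fit in 1000 draws. The form of the simulation was changed after its output had been seen, to keep the covariance of the design.

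Alternatives planned before the data were examined were quantile normalization of genes, limma without trend and robust estimation, no filter, a mean value of at least 5, a pseudocount of 0.1, a fit of the groups of the contrast alone, the replicate number as a block, array weights, and leaving out each library. Alternatives chosen after the data were seen were a batch term for the libraries with testis germ cell transcripts, leaving control replicate 3 out of contrasts that do not contain it, and quantile normalization for the gene lists. The relation of groups was also tested on other splits of the libraries.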

Results

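RNA from frozen kidneys of ICR mice, an outbred strain, aged 10 weeks, was sequenced in 18 libraries that the labels place in 6 groups of 3. The groups were untreated controls, mice given AOS at 10 mg/kg, mice on a high fat diet (HFD), HFD mice given AOS at 10 mg/kg (HFD+AOS), HFD mice that received faecal microbiota transplantation (FMT, the transfer of gut microbes from a donor) labelled AOS 10 mg/kg (HFD+AOS-FMT), and HFD mice that received a control FMT (HFD+control-FMT). AOS is used as the labels give it, without a full name. The labels do not say that the libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical. The values are normalized signals per gene, 12031 genes were tested, and differences are on the log2(value + 1) scale, which understates the change of genes with low values. The number of reads is unknown. From the step size of low values, the relative depth of the libraries ran from 0.87 in control replicate 3 to 1.031, control replicate 1 was at 0.901, and the other 16 libraries lay between 0.971 and 1.031.

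Kap, the androgen-regulated protein of the mouse proximal tubule, took 17.2% to 22.9% of the summed values in 17 libraries and 2.48% in control replicate 3. That library correlated with the others at r = 0.948 to 0.963 across genes, and the other 17 correlated among themselves at 0.979 to 0.993. All 8 adrenal gland genes on the list were at least 10 times higher in control replicate 3 than in any other library, with Star, which carries cholesterol into mitochondria for steroid synthesis, at 124.64 against at most 1.08. The tubule injury genes Havcr1 and Lcn2 stood at 19.36 and 35.12 in the same library. Transcripts of testis germ cells such as Prm1, a protamine that packs sperm DNA, were listed in control replicates 1, 2 and 3 and in HFD replicates 1 and 2, where 10 germ cell genes summed to 32.55 to 50.11, against at most 0.54 in the other 13 libraries. These 10 were taken from a list of 32, written after its genes had been seen, for a mean of at least 1 in the 5 libraries and values under 0.5 in the 13, so the gap follows in part from the choice. Every comparison with the control or HFD group contains these libraries, so the count of genes that passed in each comparison is also given without control replicate 3 and with the germ cell split as a batch term, both chosen after the data were seen.

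**Figure D1:**
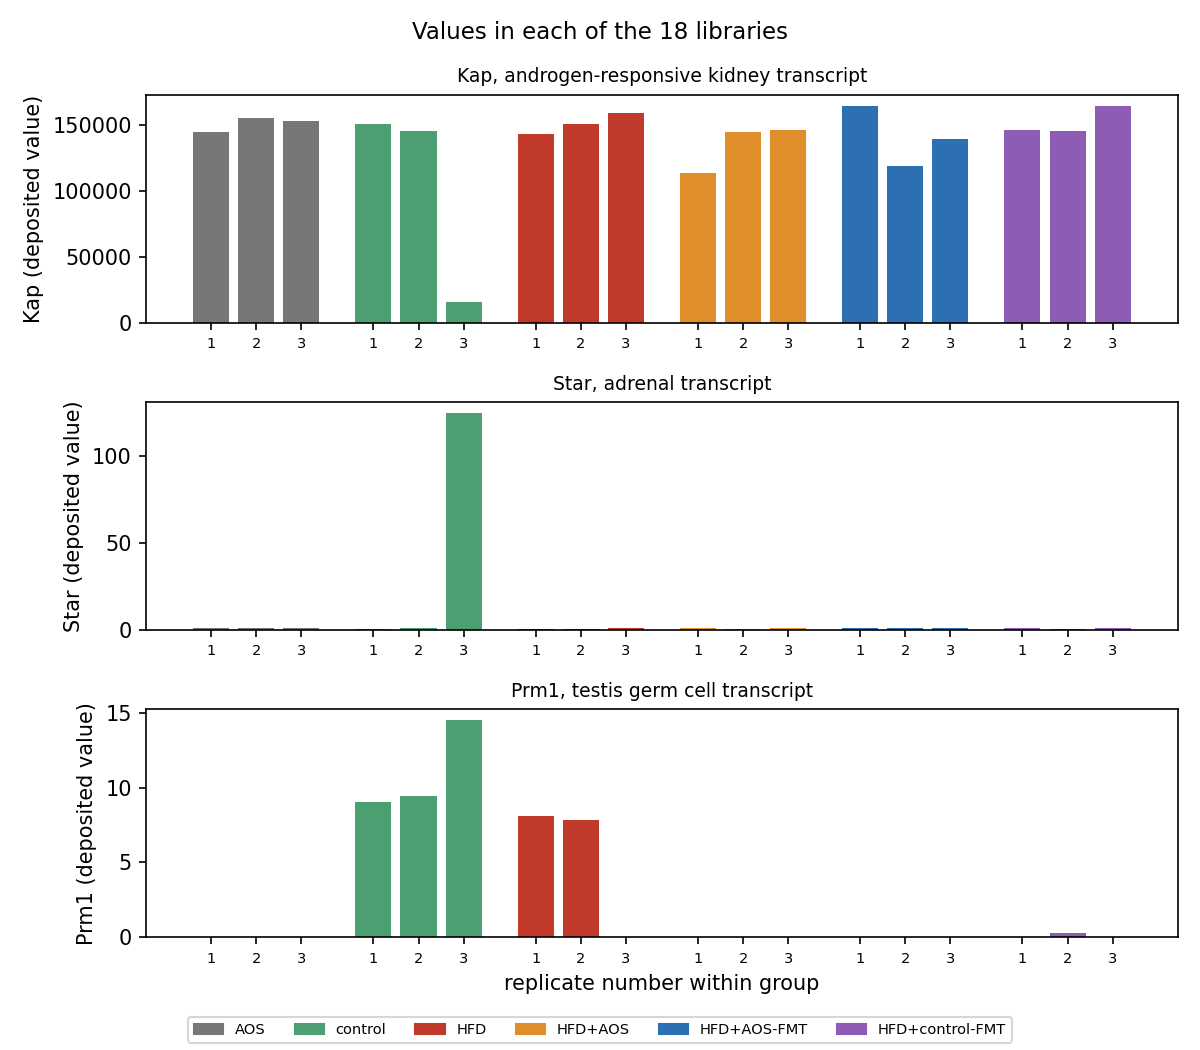
Bars give the normalized signal of Kap, Star and Prm1 in each of the 18 libraries, coloured by group, on axes that start at 0. Control replicate 3 has the lowest Kap and a Star signal of 124.64, and Prm1 is present in the 3 control libraries and in HFD replicates 1 and 2.

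The comparison of HFD with control libraries asks what the diet alone changed in the kidney. Egf, the growth factor made by the distal nephron (chromosome 3, 129677565 to 129755316, minus strand), stood at 177 ± 32.7 in HFD and 284 ± 37.6 in controls (SD, n = 3 in each group, log2 difference -0.68). Aadat, an aminotransferase of lysine and kynurenine breakdown (chromosome 8, 60505932 to 60545677, plus strand), stood at 132 ± 10.4 against 221 ± 6.03 (log2 difference -0.75). Klk1, the tissue kallikrein of the distal nephron, was at 1151 ± 108 against 1789 ± 279, and Cyp4a12b, a fatty acid hydroxylase, at 2.89 ± 0.783 against 8.38 ± 2.30. Akr1b3, the aldose reductase, was at 120.2 ± 14.5 against 76.8 ± 2.38, Lrp12 at 8.45 ± 3.26 against 3.11 ± 0.643, and Dap at 31.2 ± 3.32 against 45.3 ± 4.96. Trmu, Gdf10 and the class II pseudogene H2-Ea-ps complete the 10 genes with the smallest p, with log2 differences of -0.55, -0.96 and -3.79. None of the 10 passed, with limma adjusted p of 0.136 for Aadat and 0.137 for the others.

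Grouped by the fixed lists and adjusted over the list alone, 8 of 12 collecting duct genes were lower in HFD, 5 of 13 genes of the loop of Henle and distal tubule, 4 of 9 podocyte genes, 3 of 9 tubule injury genes, 2 of 14 fatty acid synthesis genes, 1 of 16 cholesterol genes (Dhcr7) and 1 of 6 urothelium genes (Upk3b), and no listed gene was higher. The collecting duct genes included the sodium channel subunits Scnn1b (11.9 ± 0.947 against 21.8 ± 10.5), Scnn1g and Scnn1a and the anion exchanger Slc4a1. Wnk4, Cldn16 and Calb1, which handle salt, magnesium and calcium, were lower with Egf, and the podocyte genes included Ptpro, Synpo and Nphs1. Spp1 (osteopontin) stood at 215 ± 49.4 against 1115 ± 1152, with Krt18 and Clu also lower, and the fatty acid desaturases Scd1 and Scd2 at 23.1 ± 4.23 against 55.3 ± 27.1 and 8.73 ± 0.684 against 15.9 ± 6.35. In control replicate 3, which has the adrenal transcripts, the tubule injury list was 1.32 higher in its median log2 value than in the other 2 control libraries. Without that library, adjusted over the list alone, the collecting duct, podocyte and tubule injury counts were 0 and the loop and distal tubule count was 2. The log2 difference without it went from -0.73 to -0.44 for Scd2, from -0.54 to -0.39 for Dhcr7 and from -0.90 to -0.68 for Upk3b. For Scd1 it went from -1.11 to -1.53.

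As sets (camera), collecting duct genes (adjusted p = 0.000797), loop and distal tubule genes (0.00752), podocyte genes (0.0088) and myeloid genes (0.028) were lower in HFD than other genes were. These had, with an estimated correlation, adjusted p = 0.574, 0.574, 0.695 and 0.695. Proximal tubule (0.000402), androgen responsive (0.000402), immediate early and heat shock (0.000346), adipose (0.00366), unfolded protein (0.00816) and sex chromosome genes (0.0185) were higher as sets. Their values with an estimated correlation were adjusted p = 0.516, 0.516, 0.574, 0.695, 0.574 and 0.574. Relative to the control libraries, the median of all genes was -0.10 on the log2 scale and 0.01 after quantile normalization, and the 6 sets that were higher did not pass after it (adjusted p = 0.148, 0.138, 0.0584, 0.189, 0.21 and 0.11). Without control replicate 3 the proximal tubule (0.202), androgen (0.809), adipose (0.711), sex chromosome (0.983) and podocyte (0.0648) sets did not pass, and with the germ cell batch as a term the adipose (0.0877), sex chromosome (0.0877) and unfolded protein (0.0619) sets did not.

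Over all 12031 genes, limma found 0 genes past an adjusted p of 0.05, and 2091 genes (352 higher, 1739 lower) had an unadjusted p under 0.05 where chance alone gives 602. That number was 822 without control replicate 3, 3742 without control replicate 1 and 542, below chance, in a fit of these 2 groups alone. The groups did not overlap for 15.7% of genes, and chance gives 10%. Both 602 and 10% are averages under chance. With correlated genes the counts vary around them by an amount that was not computed. Counts above or below them therefore decide nothing, here and in the comparisons that follow. The count was 217 without control replicate 2, 1 without HFD replicate 1, 1 without HFD replicate 2, and 25 with no filter on low values. It was 0 without control replicate 3 and 0 with the germ cell batch as a term, which leaves the contrast resting on HFD replicates 1 and 2.

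The series title asks whether the transplant labelled AOS 10 mg/kg alters the HFD kidney, which HFD+AOS-FMT against HFD addresses. This comparison does not separate the AOS label of the transplant from the transplant itself. Both transplants are compared with each other further below, where 0 genes passed with all 18 libraries. Hmox1, the haem-degrading enzyme induced by oxidative stress (chromosome 8, 75093621 to 75100589, plus strand), fell from 50.4 ± 5.40 to 27.6 ± 1.38 (SD, n = 3 in each group, log2 difference -0.84, limma adjusted p = 0.0244). Ndrg1, a gene induced by hypoxia and stress (chromosome 15, 66929318 to 66969640, minus strand), fell from 1735 ± 96.4 to 838 ± 140 (log2 difference -1.06, adjusted p = 0.0244). Ddc, an enzyme that makes dopamine, fell from 33.5 ± 3.62 to 17.6 ± 4.51. Upp2, a uridine phosphorylase (chromosome 2, 58567298 to 58792971, plus strand), rose from 5.47 ± 1.05 to 11.7 ± 1.20 (log2 difference 0.98, adjusted p = 0.0244), and the formin Fmnl1 from 21.2 ± 1.66 to 33.9 ± 4.36.

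In all 21 genes passed, 12 higher and 9 lower in HFD+AOS-FMT, of which 1 was a predicted gene. Others that rose were Dgkh, Ngef, Hlf, Klf12, Neu2, Fcho2, Slc25a37 (mitoferrin) and Ctbs, and others that fell were Palm3, Ccdc151, Avpr1a (a vasopressin receptor), Npnt (a basement membrane protein) and Kctd17.

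Among 13 circadian clock genes, adjusted over the list alone, 7 were higher in HFD+AOS-FMT and 3 lower, and 1, Hlf, passed over all genes (32.3 ± 1.14 against 21.9 ± 1.72, adjusted p = 0.0244). The activators Arntl (chromosome 7, 113207465 to 113314126, plus strand) and Npas2 were at 1.71 ± 0.356 against 9.85 ± 1.14 and 1.10 ± 0.140 against 6.70 ± 0.720, and the repressor Per2 at 9.47 ± 2.08 against 3.26 ± 0.564. In control replicate 3 the clock genes differed from the other 2 control libraries in the same pattern (r = 0.941 across 13 genes, which are not independent replicates). Adjusted over the list alone, the chaperone genes Sdf2l1, Hspa5 and Hsp90b1 of the unfolded protein list were lower (3 of 13). The podocyte genes Ptpro and Nphs1 (2 of 9) and the proximal tubule genes Slc27a2 (1663 ± 46.4 against 1228 ± 16.6) and Slc9a3 (2 of 16) were higher. In the same way Egf (269.5 ± 30.4 against 177 ± 32.7), the lipid sensor Ppara (17.1 ± 0.870 against 10.97 ± 0.694), Ren1, the renin gene (56.8 ± 8.39 against 28.6 ± 7.02), Cd79b and the sterol enzyme Cyp51 were higher, and Fdps, Aldoa and Tyms lower.

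**Figure D2:**
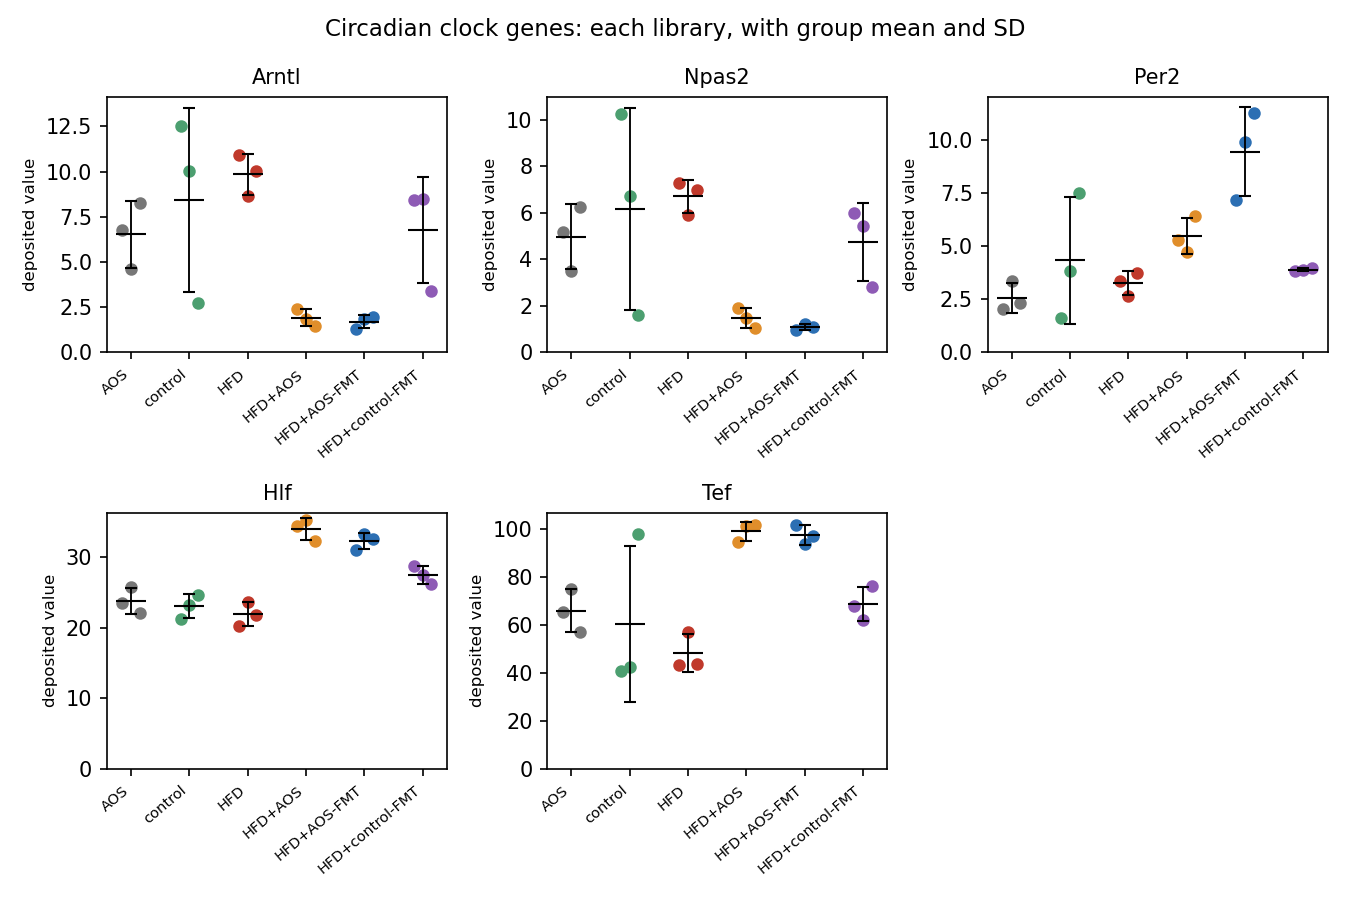
Points give the normalized signal of the clock genes Arntl, Npas2, Per2, Hlf and Tef in each library by group, with the group mean and SD (n = 3). Arntl averages 1.91 in HFD+AOS and 1.71 in HFD+AOS-FMT against 9.85 in HFD, and control replicate 3 is the lowest control library at 2.71.

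As sets (camera), podocyte genes were higher (adjusted p = 0.0397) and matrix genes (0.0442) and adipose genes (0.011) lower in HFD+AOS-FMT than other genes were. Each of the 3 had an adjusted p = 0.931 with an estimated correlation, and 1 set passed without HFD replicate 1, HFD replicate 3 or HFD+AOS-FMT replicate 3. With the germ cell batch as a term the podocyte set had an adjusted p = 0.609. No adipose gene passed over the list alone, and adiponectin (Adipoq) stood at 7.36 ± 4.85 against 21.03 ± 12.9. The clock list went both ways and passed the test for change in either direction (fry, mixed adjusted p = 0.00418). It did not pass camera (adjusted p = 0.11), and after quantile normalization it did (0.014, higher). Leaving out 1 library gave 0 genes without HFD replicate 1 or any 1 of the HFD+AOS-FMT replicates. It gave 4 without HFD replicate 2, 3 of them among the 21. Without HFD replicate 3 it gave 10 (2 higher, 8 lower), 2 of them among the 21. The count was 9 (3 higher, 6 lower) after quantile normalization, 13 without trend and robust estimation, 166 in a fit of these 2 groups alone and 641 with array weights. The groups did not overlap for 25.2% of genes, with 10% by chance. Without control replicate 3, which enters only the shared spread here, 585 genes passed, among them all 21, and with the germ cell batch as a term, where HFD replicate 3 alone carries the contrast, 1 gene passed and 0 of the 21 did.

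**Figure D3:**
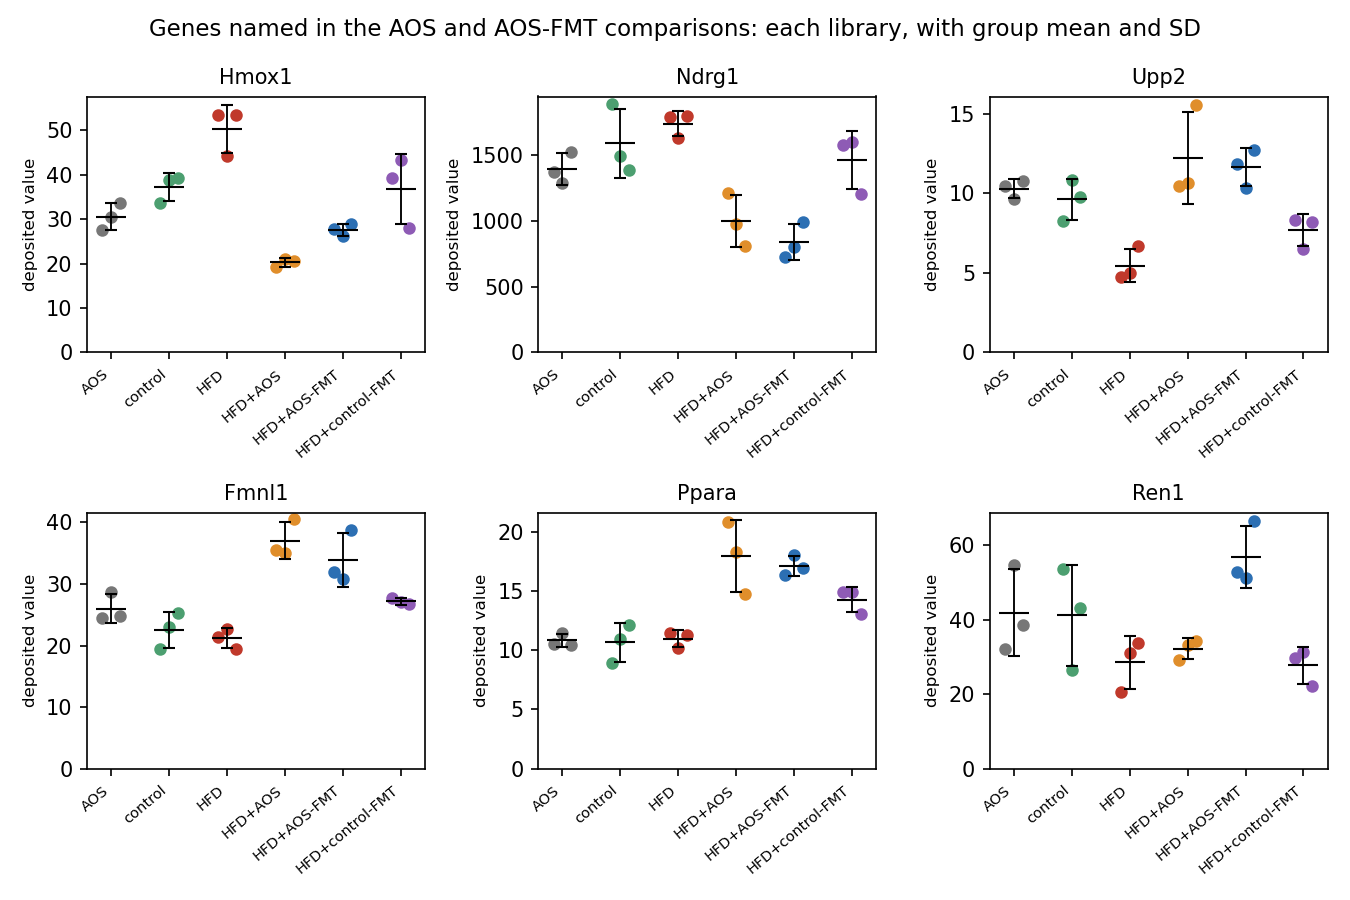
Points give the normalized signal of Hmox1, Ndrg1, Upp2, Fmnl1, Ppara and Ren1 in each library by group, with the group mean and SD (n = 3). Hmox1 averages 50.4 in HFD, 20.3 in HFD+AOS, 27.6 in HFD+AOS-FMT, 36.8 in HFD+control-FMT and 37.2 in controls.

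HFD+control-FMT against HFD gives the change with the control transplant. Grb7, an adaptor of receptor kinases, stood at 64.4 ± 4.29 against 50.6 ± 3.05 (SD, n = 3, log2 difference 0.34, limma adjusted p = 0.4995), and Gjb1, a gap junction protein, at 31.9 ± 2.13 against 22.4 ± 1.44. Trim35 was at 8.78 ± 0.701 against 13.1 ± 1.47 and the peptidase Dpp7 at 55.4 ± 5.92 against 77.3 ± 2.98. Glt1d1, Arhgef39, Ctbs, Greb1l, Hlf and Top1mt were the other genes among the 10 with the smallest p, all 6 with positive log2 differences (0.25 to 0.59). None of the 10 passed, with adjusted p of 0.4995 for Grb7 and Glt1d1 and 0.954 for the other 8. Adjusted over the list alone, Hlf (27.4 ± 1.27 against 21.9 ± 1.72, 1 of 13 clock genes) was higher, and Hmox1 (36.8 ± 7.87 against 50.4 ± 5.40, 1 of 13 antioxidant genes) and Fdps, a sterol pathway enzyme (13.4 ± 0.408 against 21.2 ± 1.47, 1 of 16 cholesterol genes), were lower.

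As sets (camera), fatty acid synthesis (adjusted p = 0.00748), cholesterol (0.0047) and adipose genes (0.00109) were lower in HFD+control-FMT and immediate early and heat shock genes (0.0047) higher. All 4 had an adjusted p = 0.882 with an estimated correlation. With the germ cell batch as a term the immediate early set had the opposite direction (adjusted p = 0.709). limma found 0 genes past the threshold, and 541 genes had an unadjusted p under 0.05 where chance gives 602. That number was 1044, above chance, without control replicate 3. Groups did not overlap for 15.4% of genes, with 10% by chance. The count was 8 without HFD replicate 3 and 1 with array weights. It was 0 without control replicate 3 and 0 with the germ cell batch as a term.

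HFD+AOS-FMT against HFD+control-FMT compares the 2 transplants on the same diet. Ddc stood at 17.6 ± 4.51 against 33.0 ± 4.70 (SD, n = 3, log2 difference -0.90, limma adjusted p = 0.203), and Ndrg1 at 838 ± 140 against 1459 ± 222. Srebf1, the transcription factor of fatty acid synthesis, was at 12.5 ± 1.25 against 7.75 ± 0.361. Agbl3 had a positive log2 difference and Pigx, Mif4gd, Grb7, Tmem120a and Prr13 negative ones, and none of these 9 genes, which are among the 10 with the smallest p, passed (adjusted p of 0.193 to 0.361). Of 13 clock genes, adjusted over the list alone, 2 (Per2 and Hlf) were higher and 2 (Arntl, 1.71 ± 0.356 against 6.77 ± 2.93, and Npas2) lower. On the same basis Ren1 (56.8 ± 8.39 against 27.8 ± 4.95), Egf and Srebf1 were higher, and Tyms, a nucleotide synthesis gene, was lower.

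Collecting duct and podocyte genes were higher as sets (camera, adjusted p = 0.0337 each), and inflammatory and immediate early genes (0.0337 each), matrix genes (0.0426), oxidative phosphorylation genes (0.0416) and antioxidant genes (0.0416) lower. With an estimated correlation, adjusted p = 0.474 for the antioxidant genes and 0.751 for the other 6. The 7 sets were 1 without HFD+AOS-FMT replicate 3 and 1 without HFD+control-FMT replicate 3. After quantile normalization the oxidative phosphorylation genes had a median of the opposite sign (adjusted p = 0.391) and the antioxidant and immediate early sets did not pass (0.459 and 0.0934). limma found 0 genes past the threshold, and 845 had an unadjusted p under 0.05 where chance gives 602. It was 1664 without control replicate 3, and below chance without HFD+control-FMT replicate 2 (482) or HFD+AOS-FMT replicate 2 (503). Groups did not overlap for 18.05% of genes, with 10% by chance. The count was 2 without HFD+control-FMT replicate 3, 1 in a fit of these 2 groups alone and 18 with array weights. It was 14 without control replicate 3 and 0 with the germ cell batch as a term, which leaves the log2 differences of this contrast unchanged, since none of its 6 libraries holds the germ cell transcripts, and changes only the spread.

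HFD+AOS against HFD compares mice given AOS directly with mice on the same diet alone. The clock genes differed between these groups, and the labels do not give the time of collection. A difference in that time cannot be told apart from AOS for any gene in this comparison. Hmox1 fell from 50.4 ± 5.40 to 20.3 ± 1.02 (SD, n = 3 in each group, log2 difference -1.26, limma adjusted p = 0.000695) and Ndrg1 from 1735 ± 96.4 to 997 ± 199 (log2 difference -0.82, adjusted p = 0.0348). Arntl, the clock activator, fell from 9.85 ± 1.14 to 1.91 ± 0.469 (log2 difference -1.91, adjusted p = 0.0399), and Msmo1, a sterol synthesis enzyme, from 30.0 ± 1.95 to 18.4 ± 1.07. Upp2 rose from 5.47 ± 1.05 to 12.2 ± 2.87 (log2 difference 1.02, adjusted p = 0.00942), Fmnl1 from 21.2 ± 1.66 to 37.1 ± 3.02 (adjusted p = 0.00495), and Ppara from 10.97 ± 0.694 to 17.9 ± 3.06 (adjusted p = 0.0225). Ugt1a7c, a glucuronidating enzyme, rose from 96.9 ± 18.8 to 161.6 ± 2.92, and Slc22a4, an organic cation transporter, from 22.0 ± 1.71 to 36.5 ± 7.84.

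In all 99 genes passed, 56 higher and 43 lower in HFD+AOS, 2 of them predicted genes and 1 a pseudogene. Others with the largest increases were Slc35f3, B3galnt1, Dhtkd1, Rsph3b, Dnajc12 and Cit, and some of those with the largest decreases Ypel2, Nt5dc2, Bcl2l15, Dynll1, Leo1, Npnt and Stx18.

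Adjusted over the list alone, 7 of 13 clock genes were higher, among them Hlf (33.9 ± 1.55 against 21.9 ± 1.72, adjusted p = 0.00234 over all genes) and Tef (99.0 ± 3.95 against 48.0 ± 7.92), and 4 lower, among them Arntl and Npas2. The chaperone gene Hspa5 (191 ± 14.4 against 274 ± 15.8), Atf4, Sdf2l1 and Hsp90b1 were lower (4 of 13 unfolded protein genes). The proximal tubule transporters Slc9a3 (adjusted p = 0.0405 over all genes), Slc6a19 and Slc27a2 were higher (3 of 16). Of 20 fatty acid oxidation genes Ppara and Cpt1a, the mitochondrial fatty acid importer, were higher and Acsl1 lower, and the synthesis genes Dgat2 and Gpam were higher (2 of 14). Vldlr, a lipoprotein receptor, passed over all genes (15.2 ± 0.770 against 12.2 ± 0.557, adjusted p = 0.0348), and adjusted over the list alone Cat and Enpep were higher and Pfkp, Aldoa, Fdps and Tagln lower.

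Proximal tubule (camera, adjusted p = 0.0356) and podocyte genes (0.0468) were higher as sets, and unfolded protein, erythrocyte, adipose and oxidative phosphorylation genes (0.0247 each), matrix and cholesterol genes (0.0329 each) lower. With an estimated correlation, adjusted p = 0.635 for the proximal tubule, unfolded protein, erythrocyte and cholesterol sets, 0.799 for oxidative phosphorylation and 0.962 for the podocyte, adipose and matrix sets. The 8 sets were 2 and 1 without HFD replicates 1 and 3, and 3 and 4 without HFD+AOS replicates 1 and 2. The oxidative phosphorylation set had an adjusted p = 0.609 after quantile normalization and the podocyte set 0.838 with the germ cell batch as a term. The count of 99 genes was 19, 24 and 16 (6 higher, 10 lower in the last) without HFD replicates 1, 2 and 3, and 10, 16 and 40 without HFD+AOS replicates 1, 2 and 3. It was 45 with no filter, 314 in a fit of these 2 groups alone and 941 with array weights, and quantile normalization gave 78 higher and 30 lower. Groups did not overlap for 28.2% of genes, with 10% by chance. A fit without control replicate 3 gave 808 genes, among them all 99, and with the germ cell batch as a term 7 passed, 5 of them among the 99. With that term HFD replicate 3 alone carries the HFD side, and the median standard error went from 0.116 to 0.167.

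**Figure D4:**
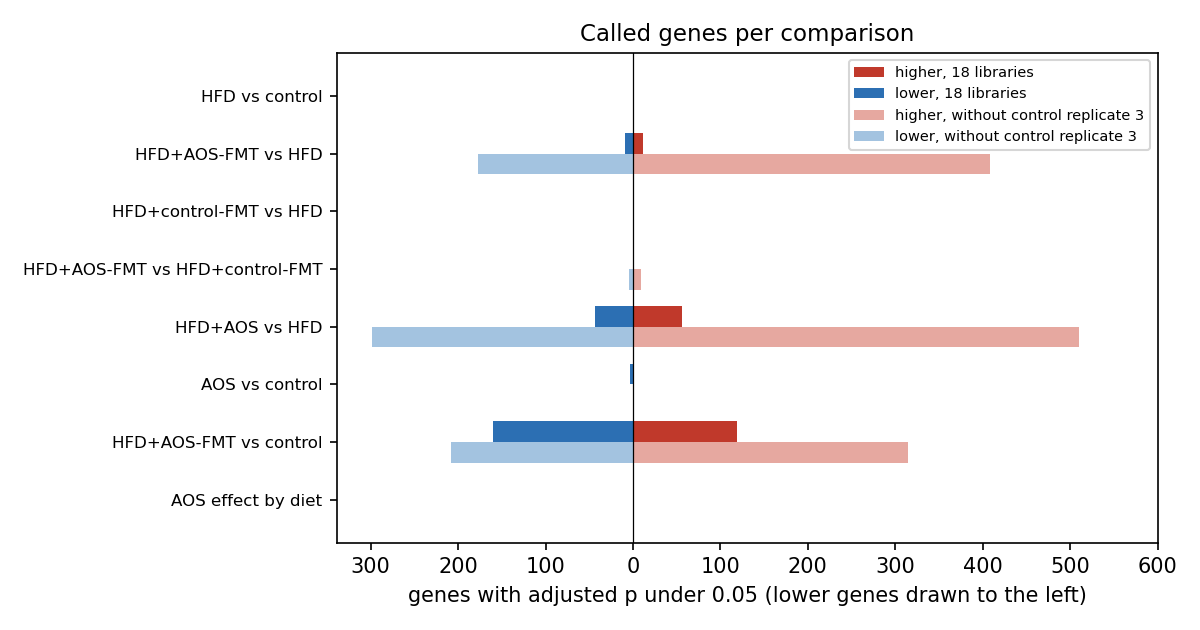
Bars give the number of genes past a limma adjusted p of 0.05 that were higher or lower in each comparison, with all 18 libraries and without control replicate 3. HFD+AOS against HFD has 99 genes with all libraries and 808 without control replicate 3, and HFD against control has 0 in both.

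AOS against control asks what AOS did without the diet. Mov10, an RNA helicase that restrains retroelements (chromosome 3, 104794836 to 104818563, minus strand), rose from 6.76 ± 0.244 to 10.6 ± 0.682 (SD, n = 3 in each group, log2 difference 0.58, limma adjusted p = 0.0327), and Dap fell from 45.3 ± 4.96 to 28.0 ± 2.13 (adjusted p = 0.0475). The germ cell genes Oaz3 (2.89 ± 0.615 in controls, adjusted p = 0.0327) and Prm1 (11.01 ± 3.04, adjusted p = 0.0499; chromosome 16, 10796326 to 10805839, minus strand) were listed at 0 in all 3 AOS libraries. All 3 control libraries hold the germ cell transcripts and no AOS library does. Tnp2, Ldhc, Tnp1, Prm2 and Fabp9, also germ cell genes, and Cyp4a12b (2.95 ± 1.09 against 8.38 ± 2.30) came next in p and did not pass (adjusted p of 0.0504 to 0.0876).

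Adjusted over the list alone, the clock repressor Cry1 was lower with AOS (0.913 ± 0.0321 against 3.06 ± 0.686, 1 of 13). So were Egf and Calb1 (2 of 13 loop and distal tubule genes), Scnn1a, Scnn1b and Scnn1g (3 of 12 collecting duct genes), Cd14 and Lyz2 (2 of 13 myeloid genes), the p53 target Cdkn1a and Upk3b. In this way 0 loop and distal tubule, 0 collecting duct and 0 myeloid genes passed without control replicate 3, Upk3b did not pass either, and the log2 difference of Cdkn1a went from -2.01 to -1.05. As sets (camera), proximal tubule (adjusted p = 2.72e-06), lymphocyte (0.0287), androgen responsive (0.00965) and sex chromosome genes (0.0364) were higher and loop and distal tubule (0.0364), collecting duct (0.0102) and fatty acid oxidation genes (0.00965) lower. With an estimated correlation, adjusted p = 0.114, 0.37, 0.647 and 0.815 for the first 4 and 0.821, 0.821 and 0.815 for the others. The 7 sets were 3 without control replicate 1 and 13 without control replicate 2. Without control replicate 3 the proximal tubule (adjusted p = 0.125), loop and distal tubule (0.167) and lymphocyte sets (0.148) did not pass, and the androgen responsive (0.247) and sex chromosome sets (0.631) had the opposite direction. The lymphocyte (0.0631), androgen responsive (0.217) and sex chromosome sets (0.0711) also did not pass after quantile normalization, nor the loop and distal tubule (0.172) and sex chromosome sets (0.558) with the germ cell batch as a term.

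In all 4 genes passed, 1 higher and 3 lower with AOS, and 1529 genes had an unadjusted p under 0.05 where chance gives 602. That number was 1043 without control replicate 3, 565 with the germ cell batch as a term and 426 in a fit of these 2 groups alone, the last 2 below chance. Groups did not overlap for 13.2% of genes, with 10% by chance. The count was 0 without AOS replicate 1, 2 or 3 and without control replicate 1 or 3, and 30 without control replicate 2. It was 1 after quantile normalization, 149 with no filter, 2 at a mean value of at least 5, 1 with array weights and 0 with the germ cell batch as a term. All 3 control libraries and no AOS library hold the transcripts, so the term rests on HFD replicates 1 and 2 against 3, and it raised the standard error to 1.85 times in the median gene.

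HFD+AOS-FMT against control sets the transplanted mice beside untreated ones. Nat8f6, an acetyltransferase gene (chromosome 6, 85808024 to 85820954, minus strand), rose from 74.2 ± 18.7 to 186 ± 12.5 (SD, n = 3 in each group, log2 difference 1.346, limma adjusted p = 0.0055), and Nudt19, a peroxisomal coenzyme A hydrolase, from 257 ± 85.9 to 735 ± 189. Cyp4a12b fell from 8.38 ± 2.30 to 1.92 ± 0.435 (log2 difference -1.66, adjusted p = 0.0055), Scd1 from 55.3 ± 27.1 to 17.9 ± 9.03, and Ppard, a lipid-sensing receptor, from 41.9 ± 28.3 to 6.44 ± 0.889. Cdkn1a fell from 34.9 ± 41.5 to 3.43 ± 1.17 (adjusted p = 0.0438) and complement C3 from 53.3 ± 49.4 to 9.43 ± 1.44 (adjusted p = 0.0499), and without control replicate 3 the adjusted p was 0.0155 for Cdkn1a and 0.0877 for C3, with log2 differences of -1.39 (from -2.35) and -1.30 (from -2.01). The protamine and transition protein genes Prm1, Prm2, Tnp1 and Tnp2, present in all 3 control libraries, were listed at 0 in HFD+AOS-FMT.

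In all 279 genes passed, 119 higher and 160 lower, 8 of them predicted genes. The others with the largest increases were Snhg11, Pzp, Bcl6, Rarres2, Zfp990, Olfm4, Col27a1, Enpp2, C8a and Tgm1, and those with the largest decreases Arntl, Gsta3 and Reep6. Of these, Bcl6 (adjusted p = 0.116), Rarres2 (0.0805) and Reep6 (0.0742) did not pass without control replicate 3, and the log2 difference went from 1.67 to 1.03 for Pzp and from -1.45 to -0.94 for Gsta3. Of 13 myeloid genes, adjusted over the list alone, 6 were lower, among them C1qb (12.03 ± 1.56 against 26.4 ± 8.87), C1qa, Lyz2 and Fcer1g, and 3 of 13 matrix genes (Tagln, Col1a1 and Col4a1). Both counts were 0 without control replicate 3. Of 13 clock genes 6 were higher and 4 lower, of 13 antioxidant genes 1 higher (Cat) and 5 lower (among them Nqo1, Hmox1 and Gpx3), of 16 cholesterol genes 1 higher (Cyp51) and 3 lower, and of 14 fatty acid synthesis genes 1 higher (Dgat2) and 2 lower (Scd1 and Scd2). Ppara, Slc27a2, Pck1, Ace and Hspa8 were higher and Calb1, Ndufa2, Aldoa, Phgdh and Bax lower, each adjusted over the list alone. Without control replicate 3 the antioxidant genes lower were 1, and Calb1, Ndufa2 and Hspa8 did not pass in this way.

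As sets (camera), proximal tubule (adjusted p = 0.000539), immediate early (0.000709), clock (0.0238), androgen responsive (0.0438) and sex chromosome genes (0.0021) were higher and myeloid (0.000539) and matrix genes (0.00201) lower. The estimated correlation gave adjusted p = 0.471 for the proximal tubule set and 0.606 for the other 6. With the germ cell batch as a term the immediate early set had the opposite direction (adjusted p = 0.861) and the clock (0.113), androgen responsive (0.0995) and sex chromosome sets (0.113) did not pass. After quantile normalization the androgen responsive set did not pass (0.246). Without control replicate 3 the proximal tubule (0.142) and sex chromosome sets (0.265) did not pass and the androgen responsive set had the opposite direction (0.554). The count of 279 genes was 792 without control replicate 2 and 61, 105 and 73 without HFD+AOS-FMT replicates 1, 2 and 3. It was 488 with no filter, 5 in a fit of these 2 groups alone and 516 with array weights, and quantile normalization gave 235 higher and 160 lower. Groups did not overlap for 16.0% of genes, with 10% by chance. A fit without control replicate 3 gave 523 genes (315 higher, 208 lower), 218 of them among the 279, and with the germ cell batch as a term 1 passed, which is among the 279. All 3 control libraries and no HFD+AOS-FMT library hold the transcripts, so that term rests on HFD replicates 1 and 2 against 3. It raised the median standard error from 0.116 to 0.213, while the log2 difference of Nat8f6 was 1.36 and that of Cyp4a12b -1.87.

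Whether the effect of AOS depended on the diet was tested as the difference between HFD+AOS less HFD and AOS less control. Hmox1 had the smallest p, with a log2 difference between the effects of -0.99 (limma adjusted p = 0.265), and stood at 30.6 ± 2.99 with AOS and 37.2 ± 3.05 in controls against 20.3 ± 1.02 and 50.4 ± 5.40 on the diet (SD, n = 3 in each group). Hlf (0.57), Tmem220 (0.80), Mdm1 (0.70), Cc2d2a (0.69), Fcho2 (0.54), Tbx2 (0.62), the predicted gene Gm14326 (1.325), Tmem192 (-0.46) and Tmem254a (-0.96) were the others of the 10 with the smallest p, and none passed. Adjusted over the list alone, the difference was positive for Egf (0.84), Ptpro (0.80), Cd14 (1.14), Ppara (0.62), Cpt1a (0.61), Vldlr (0.33) and Hlf and negative for Cd8a (-1.15), Hmox1, Arntl (-1.75) and Npas2 (-1.59). The difference was 0.53 for Ptpro and -0.98 for Npas2 without control replicate 3. That of Arntl also depends on this library, where Arntl stood at 2.71 against 12.54 and 10.05 in control replicates 1 and 2. As sets (camera), podocyte and collecting duct genes had a higher AOS effect on the diet (adjusted p = 0.0478 each), and erythrocyte (0.0458), adipose and cholesterol genes (0.0478 each) a lower one. With an estimated correlation, adjusted p = 0.766 for the erythrocyte set and 0.806 for the other 4, and without control replicate 3 none of the 5 passed (0.137 to 0.624). limma found 0 genes past the threshold, and 1490 had an unadjusted p under 0.05 where chance gives 602. The count was 1 without HFD replicate 1, 4 with no filter, 0 without control replicate 3 and 0 with the germ cell batch as a term.

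Across all 6 groups, 123 of 12031 genes passed the limma test for any difference between groups. Leaving out 1 library at a time gave 46 genes (without HFD+AOS replicate 2) to 263 (without control replicate 2), apart from control replicate 3, without which 761 genes passed, among them all 123. With the germ cell batch as a term 0 passed. That term covers the whole control group and HFD replicates 1 and 2, so it also takes up differences of these groups.

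The comparison of diet genes with the treatments asks whether treatment moved them back. As 0 genes passed in HFD against control, the planned share of reversed genes has no value. Among the 508 genes at an unadjusted p under 0.01 for the diet, 80.7% had the opposite sign in HFD+AOS-FMT against HFD, 75% in HFD+control-FMT against HFD and 74.4% in HFD+AOS against HFD. Because the same HFD libraries enter both sides, simulated unchanged groups gave a median of 93.5% with 5th to 95th percentiles of 79.7% to 99.4%, 79.3% to 99.4% and 77.5% to 99.4%, so the shares of HFD+control-FMT and HFD+AOS lay below the 5th percentile. Without control replicate 3 the shares were 68.3%, 66.1% and 67.4% of 221 genes, all below simulated 5th percentiles of 88.2%, 86.9% and 87.3%. In these simulations the diet changed no gene either, and the spread of an outlying library was not kept in its own group. A share below the simulated range therefore does not measure how far a treatment moved diet genes back. The germ cell batch term gave 58.4%, 47.2% and 47.8% of 341 genes, with simulated medians of 51.03%, 51.6% and 50.4%. The covariances of the fold changes were -0.0209, -0.0127 and -0.0186 beside simulated means of -0.0167, -0.0165 and -0.0167. HFD against control and HFD+AOS-FMT against HFD+control-FMT share no library, and their fold changes correlated across genes at r = -0.178, with a simulated SD of 0.228 around 0, and 216 of 1000 simulated values were as low. Their covariance was -0.00822 beside a simulated -0.000238. The 3 HFD libraries are too few to split.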

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

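The 5 differences between diets come from the planned test of the AOS effect by diet, and all splits of the libraries and tests of explanations in this part were chosen or worded after the results were seen.

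In 5 lists the AOS effect on the HFD less that on the control diet differed from that of all other genes, by camera on the difference itself, and whether the list medians differ between diets was not tested. On the log2 scale, HFD less control diet, the median difference was -1.09 for erythrocyte genes, -0.72 for adipose genes, 0.74 for podocyte genes, 0.45 for collecting duct genes and 0.0230 for cholesterol genes. In the erythrocyte list 5 of 7 members were negative, in the adipose list 9 of 10, while 9 of 9 podocyte and 11 of 12 collecting duct members were positive. The cholesterol list had a mean of -0.16 and was lower by the test, so its median differs from both in sign, and its median was -0.09 after quantile normalization. Adjusted p was 0.0458 for the erythrocyte list and 0.0478 for the other 4, and 0.766 and 0.806 with an estimated correlation. None of the 5 passed without control replicate 3 (0.183, 0.624, 0.162, 0.137 and 0.142 in the order given), and the erythrocyte, adipose and cholesterol lists did not pass after quantile normalization (0.142, 0.257 and 0.138). With the germ cell batch as a term the adipose (camera, adjusted p = 0.147, median -0.38) and cholesterol lists (0.0729) did not pass. The erythrocyte, podocyte and collecting duct lists passed with that term. The median of all genes was 0.11 in this contrast and -0.004 after quantile normalization. Of 100 splits of the 12 libraries, 88 called at least as many lists as the 5 observed, with a highest of 15, so chance is not excluded for the lists. For genes, 0 were called, so all 100 splits gave as many by construction, and this comparison cannot decide on chance. Among these splits 1 called 345 genes, which points to a structure of the samples. What that split separates was not tested.

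Splits of 3 against 3 libraries number 10, the real one included, too few for a share under 0.05. Where the real count was 0, every split is as large by construction. Called genes in the real split and the highest of the other splits were 0 and 1 for HFD against control (10 of 10 splits as large), 21 and 0 for HFD+AOS-FMT against HFD (1 of 10), 0 and 1 for HFD+control-FMT against HFD (10 of 10), 0 and 1 for HFD+AOS-FMT against HFD+control-FMT (10 of 10), 99 and 0 for HFD+AOS against HFD (1 of 10), 4 and 2 for AOS against control (1 of 10), and 279 and 15 for HFD+AOS-FMT against control (1 of 10). Called lists in the same order of comparisons were 10 and 12 (6 of 10 splits as large), 3 and 9 (6 of 10), 4 and 6 (6 of 10), 7 and 8 (2 of 10), 8 and 7 (1 of 10), 7 and 15 (7 of 10), and 7 and 14 (7 of 10). For the 6 groups together, 1 of 100 splits, the real one, called 123 genes or more, and the highest other called 3. A random division of the libraries thus rarely gives that count, if the libraries are exchangeable, which the labels do not establish. With the germ cell batch as a term, which also takes up differences of the control and HFD groups, the count was 0.

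Control replicate 3 stood apart from all other libraries. A female animal is argued against by the Y-linked genes, whose median ratio to the other 17 libraries was 0.703665. The scaling of the table, with Kap taking less of the total, is argued against because 755 genes stayed more than 1 log2 unit from control replicates 1 and 2 after centring on the median, against 132 between replicates 1 and 2. Adrenal tissue in the sample may account for the adrenal genes, of which 8 of 8 were at least 10 times the highest other library, but not for the low androgen responsive genes, since the log2 difference from control replicates 1 and 2 was -0.477821 in the median of the proximal tubule list and -3.23 for Kap. Of the 10 androgen responsive genes 8 were lower by more than 1 log2 unit and 2 were higher by more than 1. Against control replicates 1 and 2, 11 of 12 tubule injury, 12 of 16 inflammatory and 11 of 14 myeloid genes were higher. Whether an injured kidney accounts for the low Kap was not tested. What lowered Kap stays open, and no other biological explanation was tested because the design names none for a single control library.

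The clock genes differed between HFD and both groups labelled AOS, with Arntl at 9.85 ± 1.14 in HFD, 1.91 ± 0.469 in HFD+AOS and 1.71 ± 0.356 in HFD+AOS-FMT (SD, n = 3). The time of collection, which the labels do not give, may account for it, because the same pattern across 13 clock genes occurred inside groups, with r = 0.940751 for control replicate 3 less replicates 1 and 2 and r = 0.892217 for HFD+control-FMT replicate 3 less its replicates 1 and 2, each against HFD+AOS-FMT less HFD. HFD+AOS less HFD correlated at r = 0.937058 with HFD+AOS-FMT less HFD+control-FMT, which an effect of AOS needs, but a difference in collection time would give it as well, so it does not favour AOS. AOS against control correlated with HFD+AOS against HFD at r = 0.527. The control mean in it includes control replicate 3, and r without that library was not computed. HFD+control-FMT less HFD followed HFD+AOS-FMT less HFD with a slope of 0.375. The same 3 HFD libraries are subtracted on both sides, so a positive slope is in part built in and favours no explanation. Control replicate 3 also holds the adrenal transcripts, so its clock difference may not be that of kidney alone. Both explanations stay open, and genes are not independent replicates in these correlations. Whether a difference in collection time also reached other genes of HFD+AOS or HFD+AOS-FMT against HFD was not tested.

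Transcripts of testis germ cells occurred in control replicates 1, 2 and 3 and HFD replicates 1 and 2, with 185 genes higher in each of these 5 libraries than in any of the other 13 (21 of them on the germ cell list), a split that was chosen on such genes. A change by diet or AOS alone is argued against, because of the 6 libraries with the diet and without AOS on their labels 2 held the transcripts (median of 4 genes 6.21 and 6.4) and 4 had a median of 0. Testis RNA or reads carried into these libraries, as 1 source in fixed proportions, and a change by treatment with the transplants included cannot be told apart, since the groups hold 3 libraries each. The lowest correlation of germ cell levels between the 5 libraries was 0.899227 across 10 genes chosen for low values elsewhere, just under the value of 0.9 taken to speak for 1 source. Within HFD the median of 4 genes was 6.21 and 6.4 in replicates 1 and 2 and 0 in replicate 3. No count of HFD libraries was set to speak against a treatment, so this split could not exclude it and does not favour it. Of 8 genes of testis somatic cells 0 were higher in all 5 libraries.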

How the results depend on the processing

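The batch term for germ cell transcripts, contrasts without control replicate 3 that do not contain it, and quantile normalization of gene lists were chosen after the data were seen, and the other alternatives were planned. Called genes, with the value reported first, moved as follows, and the cause was not tested. HFD against control (0) had 25 with no filter and 1 with the groups of the contrast alone, and 0 to 217 when 1 library was left out. HFD+AOS-FMT against HFD (21) had 9 with quantile normalization (all 9 among the 21), 13 without trend and robust estimation, 166 with 2 groups alone, 641 with array weights, 585 without control replicate 3, 1 with the batch term and 0 to 10 with 1 library left out. HFD+control-FMT against HFD (0) had 1 with array weights and 0 to 8 with 1 left out. HFD+AOS-FMT against HFD+control-FMT (0) had 1 with 2 groups alone, 18 with array weights, 14 without control replicate 3 and 0 to 2 with 1 left out. HFD+AOS against HFD (99) had 45 with no filter, 314 with 2 groups alone, 941 with array weights, 808 without control replicate 3, 7 with the batch term and 10 to 40 with 1 left out. AOS against control (4) had 1 with quantile normalization, 149 with no filter, 2 at a mean of at least 5, 1 with array weights, 0 with the batch term and 0 to 30 with 1 left out. HFD+AOS-FMT against control (279) had 488 with no filter, 5 with 2 groups alone, 516 with array weights, 1 with the batch term and 61 to 792 with 1 left out. The AOS effect by diet (0) had 4 with no filter and 0 to 1 with 1 left out, and any of 6 groups (123) had 265 with no filter, 969 with array weights, 0 with the batch term and 46 to 761 with 1 left out. With the replicate number as a block, 45 genes passed in HFD+AOS against HFD (43 shared), 1 in AOS against control, 180 in HFD+AOS-FMT against control (169 shared) and 70 over the 6 groups (65 shared). The labels share only a number: same-number pairs had a median correlation of -0.0198 (45 pairs, -0.159 to 0.26, 5 over 0.1), different-number pairs 0.0115 (90 pairs), and 6 of 18 samples correlated best with their own number. Called lists were 0 with an estimated correlation and 0 with fry for a common direction in all 8 contrasts. Lists in HFD against control (10) were 5 with quantile normalization and 6 to 11 with 1 left out. Lists with the batch term were 6 in HFD+AOS-FMT against HFD (3), 7 in HFD+control-FMT against HFD (4), 11 in AOS against control (7) and 3 in the AOS effect by diet (5). They were 5 without control replicate 3 in HFD+AOS-FMT against HFD and 11 in HFD+AOS-FMT against HFD+control-FMT (7). With 1 library left out they were 1 to 4 in HFD+AOS-FMT against HFD, 3 to 7 in HFD+control-FMT against HFD, 1 to 5 in HFD+AOS-FMT against HFD+control-FMT, 1 to 9 in HFD+AOS against HFD (8), 3 to 13 in AOS against control, 5 to 9 in HFD+AOS-FMT against control (7) and 1 to 9 in the AOS effect by diet. The correlation of diet and transplant effects (-0.178) was -0.194 to -0.137 with 1 HFD library left out, -0.178 with the block, -0.194 with the batch term, -0.0757 for genes at an unadjusted p under 0.01 and -0.0625 without control replicate 3, with a simulated SD of 0.228, and 0.107 without control replicate 3. For the 239 pairs of a named gene and a comparison, 3025 of 3763 fits kept direction and side of the threshold, 553 lost it, 183 gained it and 2 reversed. The reversed values with the batch term were the log2 fold change of Prm2, AOS vs control, and the log2 fold change of Prm2, HFD+AOS-FMT vs control (0.0278 each, from -2.77), where the term takes up the germ cell libraries. Depth is unknown in absolute terms, and a fit of the groups of the contrast alone does not exist for the test over 6 groups.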

Other observations

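Every value here was chosen after the data were seen, and no test of an explanation was run for them. The class II pseudogene H2-Ea-ps stood at 0.32, 0.11 and 0 in HFD replicates 1, 2 and 3 and at 2.14 to 32.99 in the other 15 libraries, and H2-Eb1, a class II antigen-presentation gene, at 0.48, 7.01 and 1.26 in HFD against 14.4 ± 2.08 in controls (SD, n = 3). The mice are outbred, and the labels give no genotype. Hbb-bs, an adult beta globin gene, ran from listed at 0 in control replicate 1 to 1317.54 in HFD+control-FMT replicate 2, with 1.04 and 2.93 in AOS replicates 1 and 2. Ucp1, the uncoupling protein of brown fat, ran from 0.46 in HFD+control-FMT replicate 1 to 73.64 in HFD+AOS replicate 3, and within HFD+AOS the other 2 libraries stood at 1.27 and 2.00. Adipoq, the adipocyte hormone adiponectin, ran from 2.49 to 34.92.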
